A study of Mus musculus with 4 samples.

How the data were processed

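Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map dimethylation of histone H3 at lysine 79 (H3K79me2) in mouse double-negative thymocytes grown in vitro to the DN3 stage from C57BL/6 haematopoietic stem cells. Of the 4 samples, 2 were ChIP libraries, 1 from cells grown with the vehicle DMSO (control) and 1 from cells grown with A939572, an inhibitor of the stearoyl-CoA desaturase SCD1 (inhibitor). The other 2 were the matching inputs, which are not analysed here.

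The values are 2 broad peak lists, with peaks called separately for each ChIP library. BWA, MACS2 2.1.0 and the mouse build mm10 are named in the submitters' processing notes without their roles. The options of the peak caller, and whether the input served as its background, are not given in the sources used here. Each deposited peak has a position, a fold enrichment (the authors' ratio to the local background, as MACS2 writes it), the −log10 of p and the −log10 of q in the authors' columns, and a deposited score equal to the whole part of 10 times −log10 q. For broad peaks these are means over the peak, and they were used only to describe or filter peaks within a list, except for 1 test of depth in the closing section. The lowest −log10 p was 1.00 in both lists, so peaks had been kept at p up to about 0.1. The number of reads per library is not in the lists, so the depth is unknown and no level per read was computed.

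Peaks were merged where they touched and intersected with gene models in Python 3.11.15 (numpy 2.4.6, pandas 2.3.3, scipy 1.17.1). Gene bodies came from a RefSeq gene table of GRCm38.p6, the assembly that mm10 names, with 21887 protein-coding genes on chromosomes 1 to 19, X and Y. Chromosome lengths of mm10 came from GenomeInfoDb 1.38.1. The gene table gives no strand, so the planned 5′ window (the first 5 kb of each gene) and the planned promoter window could not be placed. The whole gene body, which had been fixed as another window beforehand, took its place, and a gene was called marked where peaks covered at least 50% of it. Because H3K79me2 lies mainly over the 5′ part of transcribed genes, this measure understates long genes, and the better covered 5 kb end of each gene was added as an alternative. Of the coding genes, 3841 overlap another coding gene, and a peak there cannot be given to 1 of them. These genes were left out in another alternative. A broad peak can also run past the end of a gene into its neighbour. Such peaks were not counted for coding genes, so the coverage of a named gene may belong in part to a neighbour.

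Peaks were called shared where they overlapped by at least 1 bp. Shares of peaks or genes have 95% Wilson intervals, which treat peaks and genes as independent and cover counting error only. As a description of chance overlap, the peaks of 1 list were placed at random within their chromosomes 100 times. With 1 library per condition there is no measure of the spread between replicates, so no p-value was computed for any difference between conditions. Genes were compared by the covered percent of their body in the inhibitor list minus that in the control list, and differences of at least 25 percentage points were counted. For each of 17 gene lists, the median difference was set against 10000 random lists of the same size, matched gene by gene on the mean covered percent of both libraries in up to 20 bins. The resulting percentile describes these libraries and is not a p-value. At a given mean, a higher control coverage goes with a smaller difference by construction. The percentile therefore cannot tell a smaller gain from a higher control coverage. Of 336 list entries, 335 were measured, 2 of them under a newer symbol; the remaining entry was a second name of a gene already listed.

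The groups, gene lists, comparisons and most alternatives were fixed before the data were examined. So was the rule for the genes named. It took 12 fixed genes, the 8 genes with the largest gain and the 8 with the largest loss of covered length among genes marked in 1 list only, and up to 2 genes per direction and list that differed by at least 25 points; 1 gene that this rule takes is not reported here. Alternatives were −log10 q of at least 5, fold enrichment of at least 3, a control list restricted to the covered length of the inhibitor list, merging of peaks within 1 kb, an overlap of at least 50% of a peak, ranking by q, any covered base or 80% of the gene body as the threshold, list means, and matching on gene length. A filter at q of at most 0.05 was added after the values had been seen, because most control peaks had q near 1, and so were the 5 kb gene end and the removal of overlapping genes by their whole body. The coverage, count and percentile functions were tested on simulated lists. All 200 of 200 genes set to be marked in the control list only were recovered, as were all 200 of 200 for the inhibitor list only. Each simulated peak covered more of its gene than the threshold needs, so this recovery checks the code alone. Of 200 random lists with no effect, 5 reached the top 2.5% and 8 the bottom 2.5%, and 20 of 20 changed lists reached the top 2.5%. These simulated percentiles were of list means with fewer random lists, so they do not test the medians reported here.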

Results

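H3K79me2, a histone mark deposited by the methyltransferase DOT1L over the 5′ part of transcribed genes, was mapped by ChIP-seq in mouse thymocytes at the DN3 stage, at which T cell receptor genes rearrange. The cells had been grown from haematopoietic stem cells on OP9-DL1, a bone marrow stromal line that carries a Notch ligand, with the cytokines IL-7 and Flt-3L. A939572 inhibits SCD1, the enzyme that makes oleic acid from stearic acid, and the control cells received the vehicle DMSO. The comparison asks where H3K79me2 differs when oleic acid synthesis is blocked during early T cell development. Each condition had 1 ChIP library, so values have no replicate error, and differences between conditions have no replicate check and no p-value. Wilson intervals cover counting error over genes or peaks only. Values are the authors' peak calls, and the read depth behind them is unknown.

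Peaks covered at least 50% of the gene body of 5713 protein-coding genes in the inhibitor list, 26.1% of 21887 (95% Wilson interval 25.5 to 26.7), and of 1198 in the control list, 5.47% (5.18 to 5.78). Both lists marked 954 of these genes, the inhibitor list alone 4759 and the control list alone 244. When only peaks with q of at most 0.05 were kept, 4287 genes were marked in the inhibitor list and 292 in the control list, and all 292 were also marked in the inhibitor list. None of the 292 was marked in the control list alone, which allows a share of up to 1.30%. The covered percent was at least 25 points higher in the inhibitor list for 6590 genes and at least 25 points higher in the control list for 672. At q of at most 0.05 these numbers were 5761 and 0. The direction of the gene count turned when any covered base was enough: 12110 genes then held a control peak and 11257 an inhibitor peak, but 858 and 7593 at q of at most 0.05. At the better covered 5 kb end of each gene, the lists marked 3085 and 8054 genes, a ratio of 2.61 against 4.77 over the whole body.

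Among the 12 genes fixed beforehand, regulators of T cell identity were covered in both conditions. Bcl11b, the commitment factor of T cell progenitors (chromosome 12, 107910403 to 108004145, mm10), was covered over 94.0% of its body in the control list and 100% in the inhibitor list. Tcf7, which encodes TCF1, was covered over 70.1% and 100%, although it overlaps another coding gene. Gata3, a lineage-specifying factor, was covered over 70.5% and 74.6%. Notch1, the receptor that drives T lineage entry, was covered over 42.6% in the control list and 100% in the inhibitor list. All 4 genes held peaks at q of at most 0.05 in both lists. Rag1, a subunit of the V(D)J recombinase, was covered over 83.8% in the control list by weak peaks alone and over 100% in the inhibitor list. Cd3e, a subunit of the T cell receptor complex, had no control peak and was covered over 100% in the inhibitor list by a peak with q above 0.05. Ptcra, the pre-T cell receptor alpha chain, was covered over 18.1% and 47.1%, also by weak peaks alone. Foxp3, the master regulator of regulatory T cells on the X chromosome, held no peak in either list. Some inhibitor peaks ran far past the gene. They spanned 146 kb at Notch1 (a gene of 45.9 kb) and 118 kb at Tcf7 (36.9 kb). At Rag1 the peak spanned 38.1 kb (11.3 kb) and at Cd3e 23.8 kb (10.9 kb).

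Atp2a2, which encodes the calcium pump SERCA2 of the endoplasmic reticulum (chromosome 5, 122453513 to 122502225), was covered over 32.6% in the control list and 82.8% in the inhibitor list. Its 4 control peaks all had q above 0.05, and the widest spanned 11.2 kb (122490371 to 122501560). In the inhibitor list 1 peak of 30.6 kb (122471491 to 122502139) passed q of 0.05, with a fold enrichment of 2.90 and a −log10 q of 4.70. With −log10 q of at least 5 or fold enrichment of at least 3, neither list held a peak at Atp2a2. At the better covered 5 kb end of the gene the difference was 11.6 points, against 50.2 points over the whole body. Other named genes whose difference dropped under 25 points there were Notch1 (0 points), Tcf7 (0), Dot1l (16.7), Prkca (9.48), Acadl (12.6), Stat5a (10.2), Smad3 (24.9) and Tfrc (3.66). The target of the drug, Scd1 (chromosome 19, 44394450 to 44407709), was covered over 14.5% in the control list and 97.2% in the inhibitor list. Its neighbour Scd2, another stearoyl-CoA desaturase, was covered over 77.3% and 100% by peaks that passed q of 0.05 in both lists. Dot1l itself (chromosome 10, 80755101 to 80795461) was covered over 15.8% and 74.9%.

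**Figure D1:**
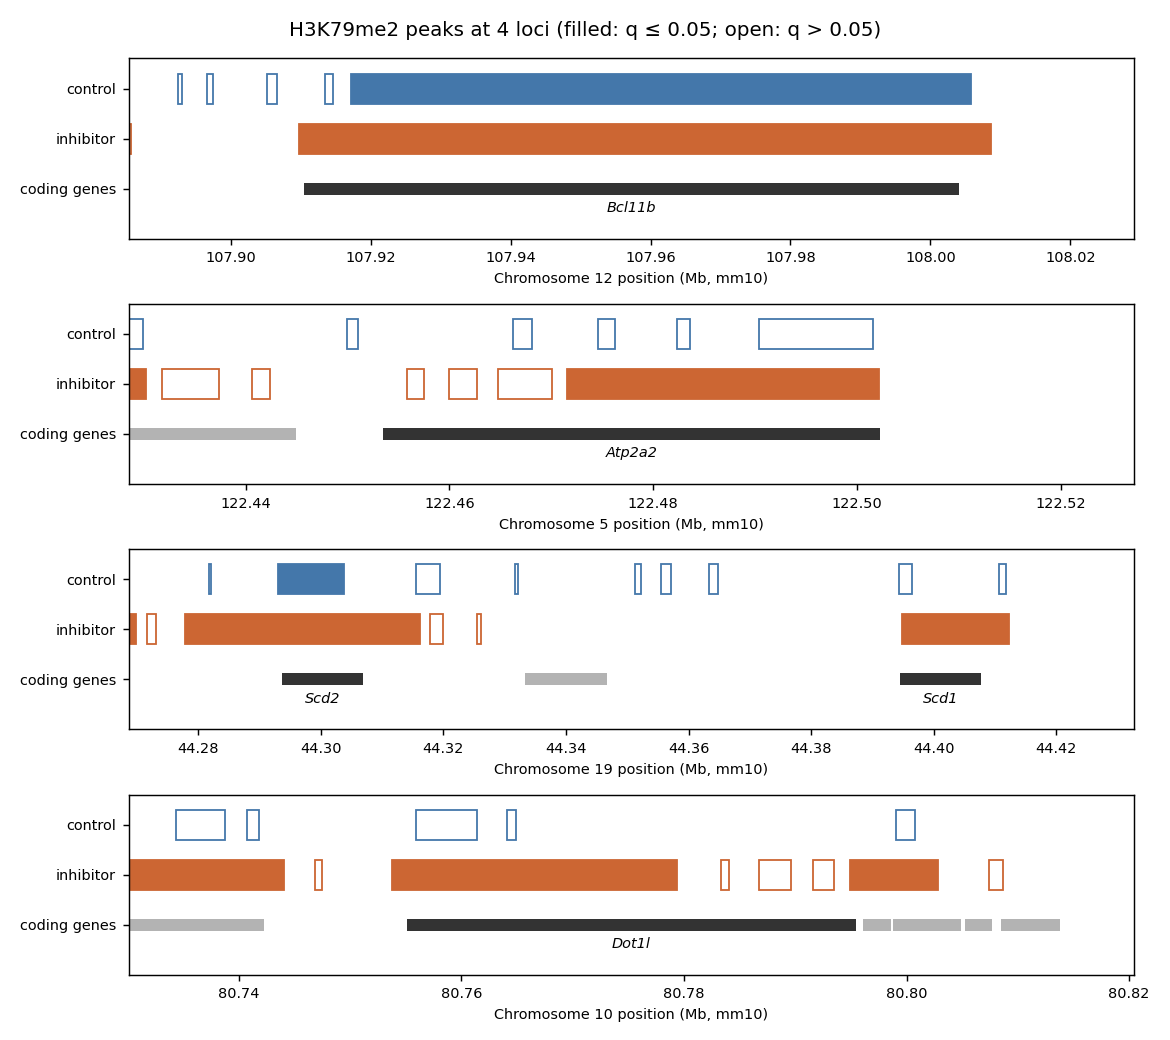
H3K79me2 peaks at Bcl11b, Atp2a2, Scd2 with Scd1, and Dot1l, with the position on the chromosome in Mb (mm10) on the horizontal axis and rows for the control list, the inhibitor list and coding genes; filled boxes are peaks with q of at most 0.05 and open boxes weaker peaks. Bcl11b and Scd2 carry filled peaks in both lists, whereas Atp2a2, Scd1 and Dot1l carry filled peaks in the inhibitor list and open peaks in the control list.

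Among genes marked in 1 list only, those with the largest gain of covered length were long, which a ranking by covered length favours. Foxp1, a forkhead transcription factor, was covered over 435 kb more in the inhibitor list (94.6% against 21.8%). Aff3, a member of the AF4 family of elongation factors, was covered over 291 kb more, and Foxn3, which overlaps another coding gene, over 283 kb more. Maml3, a Notch co-activator, was covered over 99.1% in the inhibitor list and 34.6% in the control list. Msi2, an RNA-binding protein of haematopoietic progenitors, Prkca, Atxn1 and Elmo1 were covered over 248 to 258 kb more. All 8 genes held peaks at q of at most 0.05 in the inhibitor list and none in the control list. Among genes marked in 1 list only, those with the largest loss of covered length were Cd226, an adhesion receptor of T and natural killer cells (39.5 kb less), Dthd1 (38.4 kb less), Gm5373, Rgs21, 1700057G04Rik, Wdr47, Nt5el and Zfp985 (20.8 kb less). None of these 8 held a peak at q of at most 0.05 in either list. For Wdr47 the sign turned at the better covered gene end, where the inhibitor list covered 30.1 points more.

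The called peaks differed in number and width. The control list held 124962 peaks with a mean width of 1879 bp and a median of 1286 bp, and the inhibitor list 35018 peaks with a mean of 6671 bp and a median of 1760 bp. Their covered lengths were close, 234.8 Mb and 233.6 Mb. Only 804 control peaks had q of at most 0.05, 0.643% of the list (95% Wilson interval 0.601 to 0.689). In the inhibitor list 6528 peaks passed, 18.6% (18.2 to 19.1). These stronger peaks covered 11.1 Mb in the control list, with a mean width of 13.8 kb, and 153 Mb in the inhibitor list, with a mean width of 23.5 kb. The widest peaks spanned 158529 bp in the control list and 333026 bp in the inhibitor list.

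**Figure D2:**
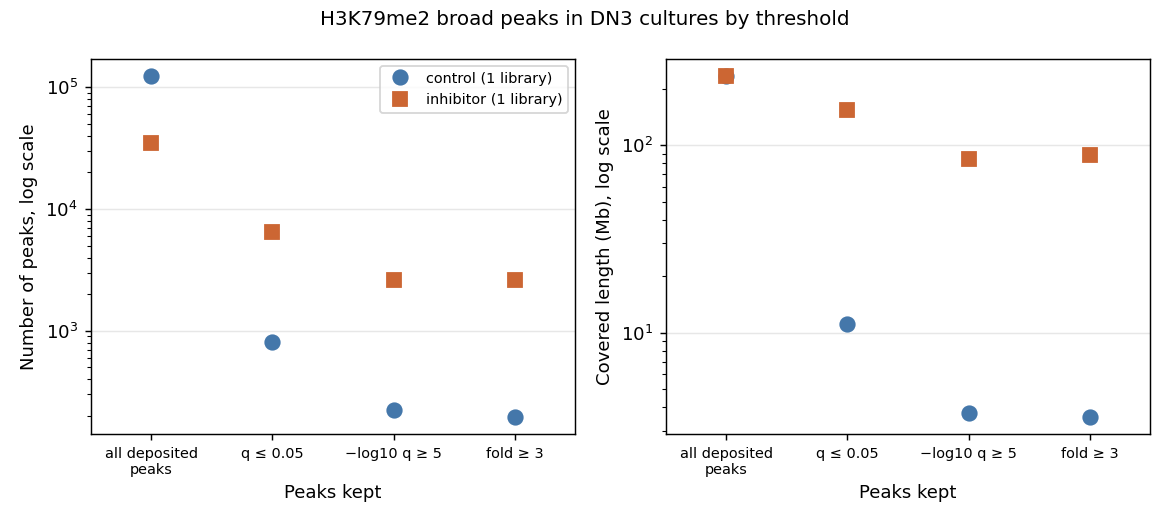
Number of peaks (left) and covered length in Mb (right), both on a log axis, for all deposited peaks and under 3 stricter filters, with 1 point per library. The control list has more peaks than the inhibitor list only when all peaks are kept (124962 against 35018); at q of at most 0.05 it has 804 against 6528.

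Of the control peaks, 21.3% (21.1 to 21.5) overlapped an inhibitor peak, against a mean of 11.02% over 100 random placements. Of the inhibitor peaks, 40.6% (40.1 to 41.1) overlapped a control peak, against 25.6% at random. At q of at most 0.05 in both lists, 98.5% of control peaks (97.4 to 99.1) overlapped an inhibitor peak, against 9.72% at random. Of the inhibitor peaks at that q, 11.8% (11.1 to 12.6) overlapped a control peak, against 1.25% at random. The placements ignored genes, which held 91.3% of the control and 91.0% of the inhibitor length at that q, against 37.9% of the genome. Part of the excess over random can therefore come from both lists lying in genes. The share of inhibitor peaks at that q that overlapped such a control peak was 0.153% (0.027 to 0.862) in the weakest decile of the inhibitor list's own fold enrichment. In the strongest decile it was 53.0% (49.2 to 56.8). When all control peaks were ranked by their own fold, 38.6% of the weakest decile and 29.7% of the strongest overlapped an inhibitor peak. Ranked by q, the shares were 14.0% and 45.2%, so the order of these deciles depended on the ranking.

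**Figure D3:**
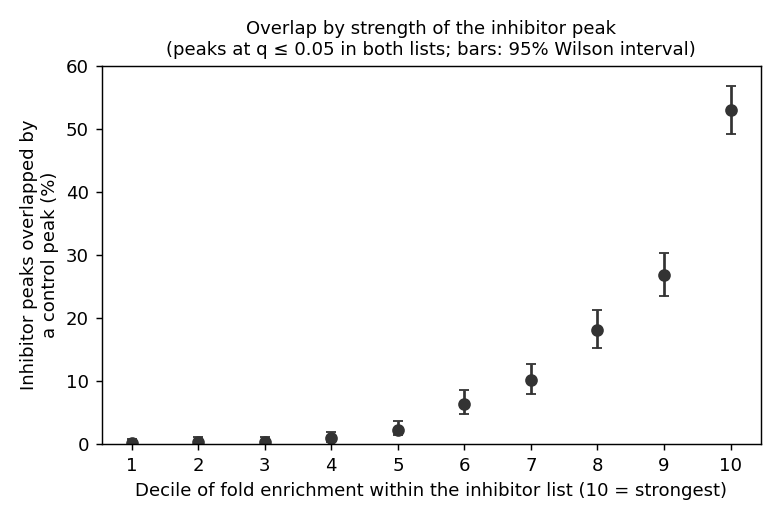
Percent of inhibitor peaks that overlap a control peak, by decile of fold enrichment within the inhibitor list, for peaks with q of at most 0.05 in both lists; bars are 95% Wilson intervals over peaks. The share is 0.153% in the weakest decile and 53.0% in the strongest.

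Gene bodies held 89.3% of the covered length in the inhibitor list and 53.3% in the control list, against 37.9% of the genome. Among peaks at q of at most 0.05 the shares were 91.0% and 91.3%. Peaks with q above 0.05 had 51.4% of their length in gene bodies in the control list and 86.2% in the inhibitor list. The inhibitor list covered more than the control list on 12 of 21 chromosomes and less on 9, from 0.678 times on chromosome 3 to 1.81 times on chromosome 11 among autosomes. The ratio was 3.13 on chromosome X and 4.998 on chromosome Y, where the inhibitor list covered 0.179 Mb and the control list 0.0358 Mb. On chromosome X the control list covered 1.05% of the sequence, against 6.06% to 12.9% of each autosome, and the inhibitor list 3.28%, against 6.84% to 15.8%. At q of at most 0.05 the inhibitor list covered 10.8 to 25.6 times the control length on chromosomes 1 to 19 and X.

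T-lineage specification genes had the highest median covered percent of the 17 gene lists in the control library, 52.4%, against 97.3% in the inhibitor library. Of 32 measured, 17 were marked in the control list and 28 in the inhibitor list, and 10 and 25 at q of at most 0.05. The covered percent was at least 25 points higher in the inhibitor list for 22 of them and at least 25 points lower for 0. The largest differences were at Cd3e and at Zfpm1, a GATA cofactor, which was covered over 4.42% and 89.7%. The median difference of the list was 30.6 points, at percentile 1.91 among random lists of like mean coverage, so below most of them. Because the matching used the mean of both libraries, the high control coverage of these genes by itself lowers this percentile. The list stood at percentile 1.14 for peaks at q of at most 0.05, but at 97.7 at the better covered gene end, 49.1 by the mean in place of the median and 41.3 at −log10 q of at least 5, so its place depended on the measure. Of 20 T cell receptor signalling genes, 7 were marked in the control list and 15 in the inhibitor list, with a median difference of 28.1 points at percentile 1.01, at 4.35 by the mean, and at 35.7 for peaks at q of at most 0.05. Bcl10, an adaptor to NF-κB, was covered over 20.2% and 99.2%, and Ptpn6, the phosphatase SHP-1, over 0% and 74.1%.

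Of 30 genes for calcium handling and NFAT, 6 were marked in the control list and 21 in the inhibitor list, and 1 and 16 at q of at most 0.05. The difference was at least 25 points in favour of the inhibitor list for 20 genes and in favour of the control list for 0. Orai1, the pore of the store-operated calcium channel, was covered over 14.5% and 100%, and its relative Orai3 over 0% and 100%. The median difference of 32.5 points stood at percentile 5.60 among random lists, and at percentile 75.1 for peaks at q of at most 0.05.

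Of 28 genes for fatty acid and sterol synthesis, 3 were marked in the control list and 21 in the inhibitor list, and 22 differed by at least 25 points in favour of the inhibitor list. The largest differences were at Scd1 and at Elovl1, a fatty acid elongase, covered over 0% and 99.1%, although it overlaps another coding gene. The median difference was 51.6 points, at percentile 98.0 among random lists, at 56.5 at the better covered gene end and at 20.6 for peaks at q of at most 0.05. Of 24 genes for fatty acid oxidation and uptake, 0 were marked in the control list and 10 in the inhibitor list (percentile 86.6). At q of at most 0.05 these were 0 and 5, with a median difference of 0 points at percentile 20.3. Ppard, a nuclear receptor for fatty acids, was covered over 1.71% and 86.4% by weak peaks alone, and Acadl, a mitochondrial dehydrogenase, over 23.6% and 100%. Cd36, a fatty acid transporter, was covered over 29.8% in the control list and 0.502% in the inhibitor list, by weak peaks alone.

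Of 18 genes for H3K79 methylation and transcription elongation, 3 were marked in the control list and 16 in the inhibitor list, and 0 and 13 at q of at most 0.05 (percentile 89.0 for all peaks). Hexim1 and Cdk9, the inhibitor and the kinase of the elongation factor P-TEFb, were covered over 0% and 21.6% in the control list and over 100% each in the inhibitor list. Of 24 regulatory T cell genes, 8 were marked in the control list and 14 in the inhibitor list, with a median difference of 29.5 points (percentile 86.3). With peaks at q of at most 0.05, 3 and 11 were marked, with a median difference of 5.44 points (percentile 28.0). Stat5a, a mediator of IL-2 and IL-7 signals, was covered over 27.9% and 100%, and Smad3, a mediator of TGF-β signals, over 27.5% and 94.3%. Of 19 cell cycle genes, 4 and 18 were marked (percentile 88.3), with the mitotic kinases Plk1 at 0% and 89.5% and Aurkb at 10.8% and 100%. Of 15 housekeeping genes, 6 and 15 were marked (percentile 12.8), with Gapdh at 40.6% and 100% and Eef2 at 30.0% and 100%.

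Of 20 stem and progenitor regulators, 1 was marked in the control list and 4 in the inhibitor list (percentile 24.3). Mycn was covered over 11.1% and 100% and Lyl1, which overlaps another coding gene, over 0% and 91.7%, whereas Mef2c was covered over 39.0% by weak control peaks and 0.239% in the inhibitor list. Of 16 genes of later T cell stages, 2 and 4 were marked (percentile 34.6). Ccr7, a chemokine receptor, was covered over 0% and 81.5% by a peak with q above 0.05, whereas S1pr1 was covered over 82.7% by weak control peaks and 0% in the inhibitor list.

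Markers of the OP9 feeder layer gave 0 marked genes of 20 in the control list and 1 in the inhibitor list, Thbs1 (11.8% and 59.0%), with Pdgfrb at 9.18% and 45.3% (percentile 50.5). B cell markers gave 0 and 1 of 13, the latter being the kinase Blk (22.2% and 75.3%; percentile 60.3). Myeloid markers gave 0 and 2 of 14, Cd68 and Fcer1g (percentile 64.8). Natural killer and innate lymphoid markers gave 4 and 6 of 12 (percentile 28.6), with Zbtb16, which overlaps another coding gene, at 19.2% and 84.7%, and all 6 passed at q of at most 0.05. Klrb1c was covered over 40.2% and Klrd1 over 35.1% by weak control peaks alone, and 0% each in the inhibitor list. For Klrd1 the difference was −12.4 points when the control list was restricted to the covered length of the inhibitor list. Erythroid and megakaryocyte markers gave 0 and 1 of 10, the transferrin receptor gene Tfrc at 36.4% and 99.5% (percentile 50.02). Its highest peak fold went the other way, 5.22 in the control list and 4.03 in the inhibitor list. Fold is a mean over each peak, and this control peak spanned only 6.98 kb. Itga2b was covered over 0% and 28.3% and Pf4 over 31.4% and 0%, both by weak peaks alone. None of 20 tissue genes silent in blood was marked in either list (percentile 50.4). The feeder, B cell, myeloid, erythroid and megakaryocyte, silent tissue and later T cell lists each had a median difference of 0 points. The median of their random lists was 0 points as well. Ties are placed at their middle rank, so these percentiles are set largely by ties and say little about a difference. Of the 17 lists, 1 stood in the top 2.5% of its random lists and 2 in the bottom 2.5%.

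**Figure D4:**
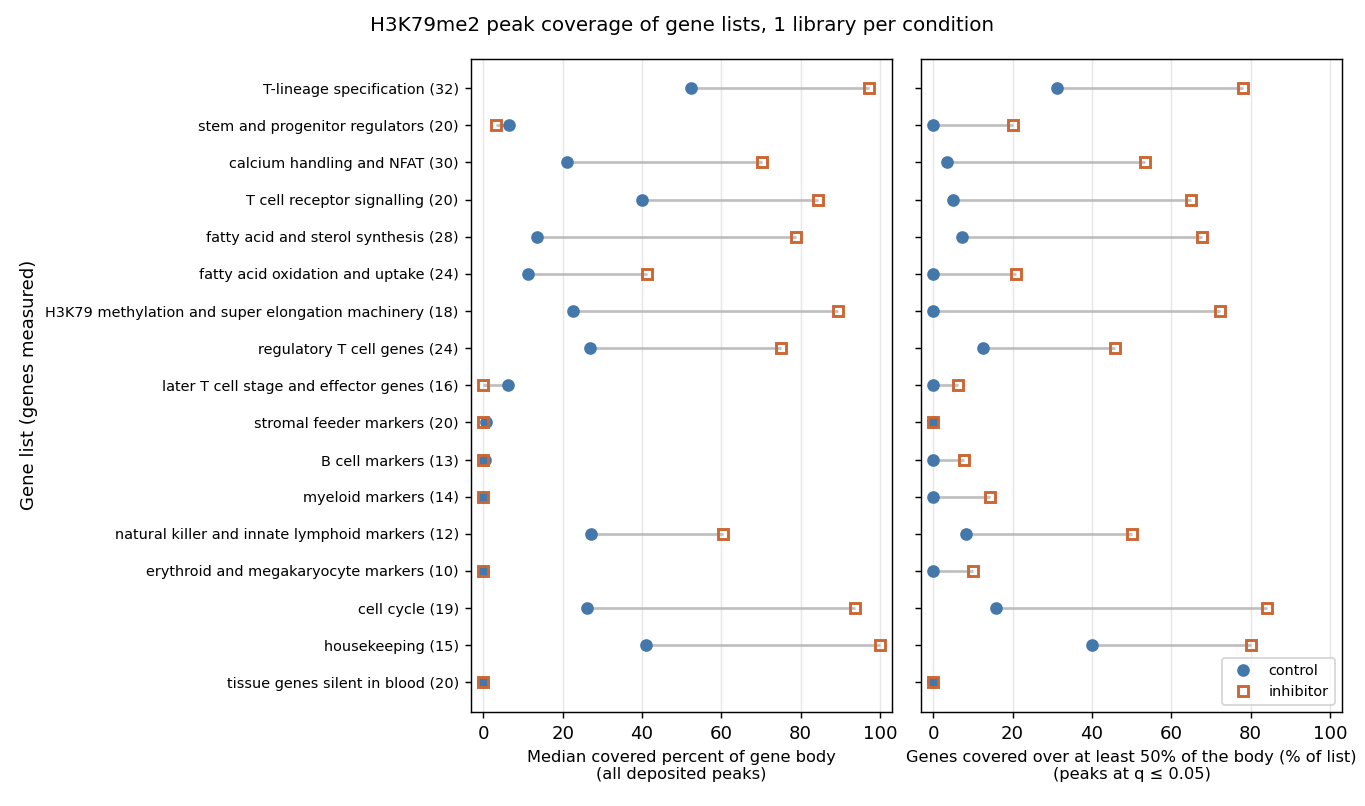
Median covered percent of the gene body with all deposited peaks (left) and percent of genes covered over at least 50% of the body with peaks at q of at most 0.05 (right), for 17 gene lists with the number of genes measured in parentheses; circles are the control and squares the inhibitor library. T-lineage specification genes have medians of 52.4% and 97.3%, and tissue genes silent in blood have 0% in both.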

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

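The test in this part was chosen after the peak lists had been seen. Long non-coding RNA genes lie outside the comparison of protein-coding genes. Of 5742 such genes more than 10 kb from any coding gene, 73 were covered over at least 50% at q of at most 0.05 in the inhibitor list, 1.27% (95% Wilson interval 1.01 to 1.595). In the control list 6 were, 0.104% (0.048 to 0.228), and all 6 were also covered in the inhibitor list. This was picked out as a signal above the control level in genes that no comparison used. Coding genes differed in the same direction at that q, with 4287 marked in the inhibitor list (19.6%) and 292 in the control list (1.33%). The difference is therefore not particular to non-coding genes. Of the 73 genes, 10 lay in an inhibitor peak at that q that also reached a coding gene, and the other 63 did not. The longest, 2610307P16Rik on chromosome 13, was covered over 95.9% of its 425389 bp in the inhibitor list and 37.1% in the control list. Lncpint on chromosome 6 was covered over 100% in the inhibitor list and 0% in the control list at that threshold, and Gm4258 on chromosome 1 over 100% and 53.7%. These genes were named after their values were seen. With all deposited peaks, 137 of these genes were covered in the control list and 136 in the inhibitor list.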

How the results depend on the processing

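The filter at q of at most 0.05, the 5 kb gene end and the removal of overlapping genes were chosen after seeing the data. No paired analysis was possible because each condition had 1 ChIP library, and for the same reason no library could be left out. The 5′ window and the promoter window were not run, since no strand was given; merging within 1 kb changed nothing, as no peaks lay that close. The excess of marked genes in the inhibitor list held under every filter on peaks and every gene window tried, with any covered base as the exception. At q of at most 0.05 the control and inhibitor lists kept 804 and 6528 peaks over 11.1 and 153 Mb (mean widths 13.8 and 23.5 kb); overlap was 98.5% of control and 11.8% of inhibitor peaks and 7.18% of the union, against 18.4% with all peaks. The weakest and strongest control deciles then overlapped at 97.53% and 95.1%, and the control gene body share was 91.3%. The control list marked 292 genes, both lists 292 and the control alone 0. At −log10 q of at least 5 the lists kept 225 and 2609 peaks over 3.71 and 84.1 Mb (16.5 and 32.2 kb), with overlaps of 96.4%, 8.28% and 4.37%. They marked 122 and 2412 genes, 121 in both, 1 in the control alone and 2291 in the inhibitor alone. At fold enrichment of at least 3 they kept 195 and 2616 peaks over 3.54 and 88.5 Mb (18.2 and 33.8 kb), with overlaps of 94.9%, 6.995% and 3.96%. They marked 101 and 2323 genes, 99 in both, 2 in the control alone and 2224 in the inhibitor alone. Requiring 50% of the peak gave overlaps of 18.0% and 13.9%, and 34.1% and 27.2% in the weakest and strongest control deciles; ranking by q gave 14.0% and 45.2%. With any covered base, 12110 control and 11257 inhibitor genes counted, 8577 in both, 3533 in the control alone and 2680 in the inhibitor alone. With 80% covered the numbers were 326, 3241, 212, 114 and 3029. The better covered 5 kb end gave 3085 control and 8054 inhibitor genes, 2500 in both, 585 in the control alone and 5554 in the inhibitor alone, a ratio of 2.61 against 4.77. Lists in the top 2.5%, 1 with all peaks, numbered 0 at q of at most 0.05, 0 at fold of at least 3, 0 without overlapping genes and 2 when also matched on gene length. Lists in the bottom 2.5%, 2 with all peaks, numbered 1 at q of at most 0.05, 1 at −log10 q of at least 5, 0 at fold of at least 3, 1 at the gene end and 1 without overlapping genes. Their members were T-lineage and T cell receptor signalling genes with all peaks, T-lineage genes at q of at most 0.05 (percentile 1.14), T cell receptor signalling genes without overlapping genes (2.39), housekeeping genes at −log10 q of at least 5 (percentile 0.265) and at the gene end (0.33), and later T cell genes (0.43) and silent tissue genes (0.55) by list means. Merging and the restriction to equal covered length left the lists nearly as they were. Under the other alternatives, 193 values of named genes stayed on their side of 25 points, 110 crossed it and 1 reversed, Wdr47 at 30.1 points at the gene end. Of the 193, 56 came from leaving out overlapping genes, which cannot change the value of a gene that remains. For the differences of gene lists, which matching on length leaves as they are, 84 stayed and 18 crossed under the remaining alternatives. The cause of these changes was not tested beyond the filters' own construction. The unknown read depth limits every count, since the number of peaks called grows with depth.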

Other observations

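The gene families, receptor loci, strongest peaks, implied background, missing control genes and decile test in this part were chosen after the result was seen; the tests of weak control peaks and of Atp2a2 against like genes were set before their results. Of 84 cytosolic ribosomal protein genes, 15 were marked at q of at most 0.05 in the control list and 81 in the inhibitor list, with their many pseudogenes not treated separately. Of 11 serine and arginine rich splicing factor genes, 6 and 10 were marked, and of 21 heterogeneous nuclear ribonucleoprotein genes 10 and 20. Of 39 proteasome subunit genes, 0 and 26 were marked, and of 75 mitochondrial ribosomal protein genes 2 and 36. None of 53 keratin genes was marked in either list. Of 1106 olfactory receptor genes, 117 were marked in the control list and 6 in the inhibitor list with all peaks, and 0 and 1 at q of at most 0.05. Of 353 vomeronasal receptor genes, 8 and 0 were marked with all peaks.

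The constant regions of the T cell receptor beta and gamma loci (Trbc1, Trbc2, Trgc1, Trgc2 and Trgc4) were covered over 100% at q of at most 0.05 in both lists. Trdc, the constant region of the delta locus, was covered over 59.9% in the control list and 100% in the inhibitor list. Trac, the alpha constant region, held no peak in either. Over whole loci with all peaks, Tcra was covered over 19.4% in the control list and 6.77% in the inhibitor list, Tcrb over 37.7% and 36.5%, Tcrd over 31.4% and 39.5% and Tcrg over 82.2% and 93.0%. With peaks at q of at most 0.05 the values were 1.04% and 4.74%, 5.51% and 33.7%, 8.75% and 25.1%, and 65.4% and 90.6%, in the same order. Of the 20 peaks with the highest fold in each list at q of at most 0.05, 17 of the control list had a counterpart at that q in the inhibitor list and 13 of the inhibitor list had one in the control list. Shared peaks of this kind lay over Mbnl1 and Tra2b, which encode splicing regulators, and over Pde3b. The strongest control peak (chromosome 3, 50272559 to 50273823, fold 7.13) lay outside coding genes and had no inhibitor counterpart. The strongest inhibitor peak (chromosome 1, 77373733 to 77374929) lay in Epha4 and had no control counterpart. The peak of lowest q in each list lay at the start of chromosome 9 (3023624 to 3024549 in the control list), with a fold of only 1.33 in both.

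The first pattern is that fewer control peaks pass q of 0.05 (804 against 6528) and the control list marks fewer genes. Lower effective depth in the control library was predicted to lower the local background implied by each peak's own fold and Poisson p. At 791 loci passing q of 0.05 in both lists, the control background was 1.14 times the inhibitor background (interquartile range 1.04 to 1.25). At 644 loci chosen from the inhibitor list the range was 1.10 to 1.29. The ratio goes against the prediction. The fold enrichment was higher in the inhibitor list at 748 of the 791 loci, with medians of 3.92 and 2.53 in the control list. Among 157 pairs of like width it was higher at 151 (4.90 against 2.76). How the caller set and scaled its background is not given, so neither the ratio nor these folds can decide whether depth differed. The background estimate takes each peak's mean fold as exact, and over all peaks the −log10 p at like fold was mixed. The control median was lower at folds of 1.6 to 1.8 (1.40 against 1.43, 78924 control peaks) and 2 to 2.5 (2.29 against 2.99, 3210 control peaks). It was higher at 2.5 to 3 (6.26 against 5.22, 242 control peaks), 3 to 4 (10.4 against 8.56, 147) and 4 to 5 (19.2 against 14.1, 32). Of 292 control genes at q of at most 0.05, 0 were missing from the inhibitor list. This count repeats the one given above for genes marked in the control alone at that q and is no separate test. It does not reach the 244 genes marked in the control alone with all peaks, as 0 of them held a control peak at that q. It also leaves open the 3995 genes marked in the inhibitor alone. At that q, 1318 inhibitor peaks (20.2%) and 11 control peaks (1.37%) had no peak of any strength in the other list. Lower depth or a weaker immunoprecipitation in the control library, and a gain of the mark under the inhibitor, all predict that control peaks remain at the strongest inhibitor domains. This was found (53.0% in the top decile against 0.153% in the bottom). These explanations cannot be told apart with 1 library per condition, unknown depth and no spike-in named in the labels.

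The second pattern is that 99.4% of control peaks had q above 0.05. Background calls of a lenient threshold alone, spread evenly, would overlap inhibitor peaks at q of at most 0.05 at near the random share. The overlap was above it, at 12.1%, 1.94 times the random mean of 6.22%. The placements ignored genes, which held 51.4% of the length of these control peaks against 37.9% of the genome. The excess therefore cannot tell peaks that follow the inhibitor domains from background calls that favour genes. The other 87.9% lay outside those domains. Of the 244 genes marked in the control list alone, 114 were olfactory receptor genes, 46.7% (95% Wilson interval 40.6 to 53.0) against 5.05% of all coding genes, and 0 of the 244 held a control peak at q of at most 0.05. Their median length was 1.09 kb, against 17.2 kb for all coding genes, so that 1 weak peak is enough to cover such a gene.

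The third pattern is the higher coverage of Atp2a2 under the inhibitor. If the gain were shared by genes of similar coverage, its difference would lie among theirs; at 50.2 points it stood at percentile 29.9 of 1093 genes of like mean coverage, whose median was 61.3 points. The difference of Atp2a2 was therefore smaller than that of most of these genes. The mean used for matching includes the inhibitor coverage itself, and genes were not matched on control coverage alone. Genes with little control coverage can enter this set only if their inhibitor coverage is high. The test therefore cannot decide whether the gain at Atp2a2 was shared or particular to it. Whether the higher coverage is technical or biological stays open as above.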
